A study of Mus musculus with 11 samples.

How the data were processed

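Oviducts of female CD1 mice, an outbred strain, were collected 24 h after an intraperitoneal injection given on the day of estrus, per the labels. Control mice received no lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria). The remaining mice received 2 µg of it, called the low dose here, or 10 µg, called the high dose. Total RNA was measured on the nCounter mouse miRNA assay, which ligates a tag to each miRNA, hybridises it to a fluorescent barcode and counts barcodes one by one without amplification or reads. The design text plans 4 mice per treatment. The data held here cover 11 mice: 3 control, 4 low dose and 4 high dose. The remaining control mouse was not analysed here. Each mouse is a separate animal per the labels' protocols.

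The deposited table gave barcode counts per probe and lane, handled as estimated counts because a lane quality measure with decimals shares the columns. Every probe value was already a whole number, so rounding changed nothing. It held 626 probes: 566 mouse miRNA probes, 33 viral miRNA probes, 6 positive, 8 negative and 6 ligation controls, 3 spike-in probes and 4 mRNA reference probes (Actb, B2m, Gapdh and Rpl19). No normalization by the authors was recorded, and the counting software is not given in the sources used here. The submitters' labels state that all samples met the assay maker's quality criteria. Names of 4 miRNA probes (let-7a, miR-155, miR-34c and miR-543) carried a factor above 0 whose use is not given in the sources used here. Their counts were used as deposited, and the factor times the count of the POS_A control was subtracted as an alternative.

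A miRNA was taken as detected when its count exceeded the mean plus 2 SD of the lane's negative controls in at least 3 lanes. This left 205 miRNAs, 145 of them above the bound in every lane. Counts were scaled with trimmed mean of M-values (TMM) factors over these miRNAs, and normalized counts are on the scale of the mean effective library. Tests used edgeR 4.0.16 quasi-likelihood F-tests in R 4.3.3 in a one-way model over all 11 mice, with Benjamini-Hochberg adjustment over 205 miRNAs and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The design text names a one-way analysis of variance with least significant difference contrasts. That test was run as an alternative.

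Before the data were examined, 19 miRNA lists were fixed from general knowledge of LPS responses, cell types, families and genomic clusters. The 17 with at least 3 detected members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with estimated correlation as an alternative. The cell type lists share members with each other and with the family lists. The LPS-responsive list shares 5 of its members with other lists, among them miR-203 (epithelial), miR-222 (endothelial) and miR-21 (myeloid). The miRNAs named were set by a rule fixed at the same time. It took up to 12 past the threshold per direction with the smallest p, the 5 with the smallest p where fewer than 5 passed, the detected members of the LPS-responsive list, 2 to 4 members of other lists with the smallest p, the control and mRNA probes, and the 5 most abundant miRNAs. Any other miRNA named is stated as such. The mRNA reference probes were scaled to the geometric mean of the positive controls and tested with an exact permutation of the one-way F statistic on log2 counts, which has 11550 arrangements.

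Fold changes at the low and high dose share the control mice, so their correlation was set beside 100 simulated data sets without any effect. All simulated sets drew each miRNA independently, so they hold no variation that a mouse shares across miRNAs. The fit was tested on simulated counts before use. In 5 simulated sets of 40 changed miRNAs each, which keeps most of the 205 unchanged, the high dose comparison recovered 99% of miRNAs changed by 1 log2 unit and 53% of those changed by 0.5. The low dose comparison recovered 94% and 55%. Unchanged miRNAs made up 3.80% of calls in the former and 6.29% in the latter. These shares may be too low for mice whose miRNAs vary together.

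Alternatives covered 3 other scalings, no filter and a stricter filter, background subtraction, DESeq2 1.42.0, limma-voom, other thresholds, fits to the compared groups alone, the replicate number as a block, and leaving out each mouse. Further alternatives were chosen after seeing the data: scaling to the positive controls alone, the POS_A subtraction, a bound without the negative control NEG_C, leaving out the 3 lanes with the highest NEG_C, a ligation covariate, and leaving out the 2 LPS mice with the lowest B2m. Names of neighbouring miRNA genes came from a RefSeq gene table of assembly GRCm38.p6. No coordinates are given.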

Results

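MicroRNAs were counted in the oviducts of 3 control mice, 4 mice given 2 µg of LPS and 4 mice given 10 µg, 24 h after injection. The question set by the design was which miRNAs respond to LPS in the oviduct and at which dose. Total miRNA counts ranged from 451323 to 684771 per mouse, a 1.52-fold range, and between 98.0% and 98.5% of them fell in the 205 detected miRNAs. Counting noise would give a median share of 0.0296 of the variance between mice of a group in the 102 miRNAs with the higher counts, and 0.454 in the other 103. The most abundant miRNAs were miR-125b-5p with 50197 ± 6920 normalized counts (SD, n = 11), miR-145 with 32406 ± 4204, miR-29a with 30243 ± 2526, let-7c with 26865 ± 6466 and miR-720 with 25446 ± 2292. miR-145 is typical of smooth muscle. The labels describe separate mice, and each was counted once. Chi-square per degree of freedom between mice of a group was 17.3 to 92.3, which excludes only the same lane deposited again. Lanes ran in group order, with controls in lanes 1, 2 and 4, the low dose in 5 to 8 and the high dose in 9 to 12, so lane position and treatment cannot be told apart by design.

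At the low dose, 12 of 205 miRNAs passed the edgeR quasi-likelihood test, 7 higher and 5 lower than control. miR-203, a miRNA enriched in epithelia, rose from 119 ± 10.4 to 208 ± 15.8 normalized counts (SD, n = 3 and 4), a 1.74-fold change (edgeR adjusted p = 0.00254). miR-222 rose 1.87-fold (log2 change 0.91 ± 0.14 SE, edgeR adjusted p = 0.00254), and miR-101a 1.87-fold (0.91 ± 0.18, edgeR adjusted p = 0.0120). miR-21, miR-1902, miR-26a and miR-196b rose by 0.52, 0.83, 0.61 and 0.65 on the log2 scale. Among those lower, miR-23a fell from 7459 ± 475 to 5540 ± 211 normalized counts, and miR-27a, which shares its gene cluster, from 6065 ± 257 to 4241 ± 202. miR-30c fell by 0.52, miR-322 by 0.61 and miR-301a by 0.39 on the log2 scale. In all 12, the 4 low dose mice lay outside the range of the 3 control mice. Chance gives this for 5.71% of unselected miRNAs, and choosing miRNAs by their test favours it. Of 27 alternatives, the call of miR-26a ended in 16, of miR-196b in 13, of miR-21 and miR-322 in 10 each, of miR-301a in 9 and of miR-27a in 8, against 1 each for miR-203 and miR-222. With nCounter-style scaling 12 of 17 calls were higher, and with scaling to the positive controls alone 8 of 8, against 7 of 12 here.

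Of the 15 miRNAs listed beforehand as LPS-responsive, 11 were detected. At the low dose 3 of them rose (miR-203, miR-222 and miR-21), none fell and 8 did not pass; adjusted over the list alone, 5 rose. miR-146a, a negative regulator of Toll-like receptor signalling, stood 0.82 ± 0.24 SE above control (edgeR adjusted p = 0.0548), and miR-155 0.39 ± 0.13 (edgeR adjusted p = 0.0767). The list as a whole stood above the other miRNAs (camera adjusted p = 0.0288), which became adjusted p = 0.398 with an estimated correlation. Its call at this dose ended without control mouse 1, control mouse 2, low dose mouse 1 or low dose mouse 4, with scaling to the positive controls alone, and without the filter on low counts (adjusted p = 0.117). Among the other lists at the low dose, miR-23a, miR-27a and miR-21 changed in the myeloid list, miR-222 in the endothelial, miR-203 in the epithelial, miR-30c in the miR-30 family and miR-322 in the miR-15/16 family and the ovary and oocyte list, with camera adjusted p from 0.437 to 0.955 over the 16 lists. Adjusted over the list alone, 4 of the miR-30 family rose and 1 fell, 2 myeloid miRNAs rose and 3 fell, 1 epithelial rose and 1 fell, and 2 other organ miRNAs rose. The count of 12 fell to 6 without control mouse 1, 4 without control mouse 2 and 3 without low dose mouse 4. It fell to 0 in edgeR when counts were scaled to the mRNA reference probes. Without that scaling it was 56 at an unadjusted p under 0.05 and 20 with DESeq2. DESeq2 gave no adjusted p for 60 miRNAs here, so its count is adjusted over fewer. With mRNA scaling all 12 kept their sign, with miR-203 at 0.62 ± 0.38 SE, miR-222 at 0.74 ± 0.38 and miR-23a at -0.63 ± 0.35. The median standard error of the 12 grew from 0.131 to 0.363. That scale includes B2m, which itself stood 1.92 above control at the low dose (log2), against -0.03, -0.29 and -0.0027 for Actb, Gapdh and Rpl19.

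**Figure D1:**
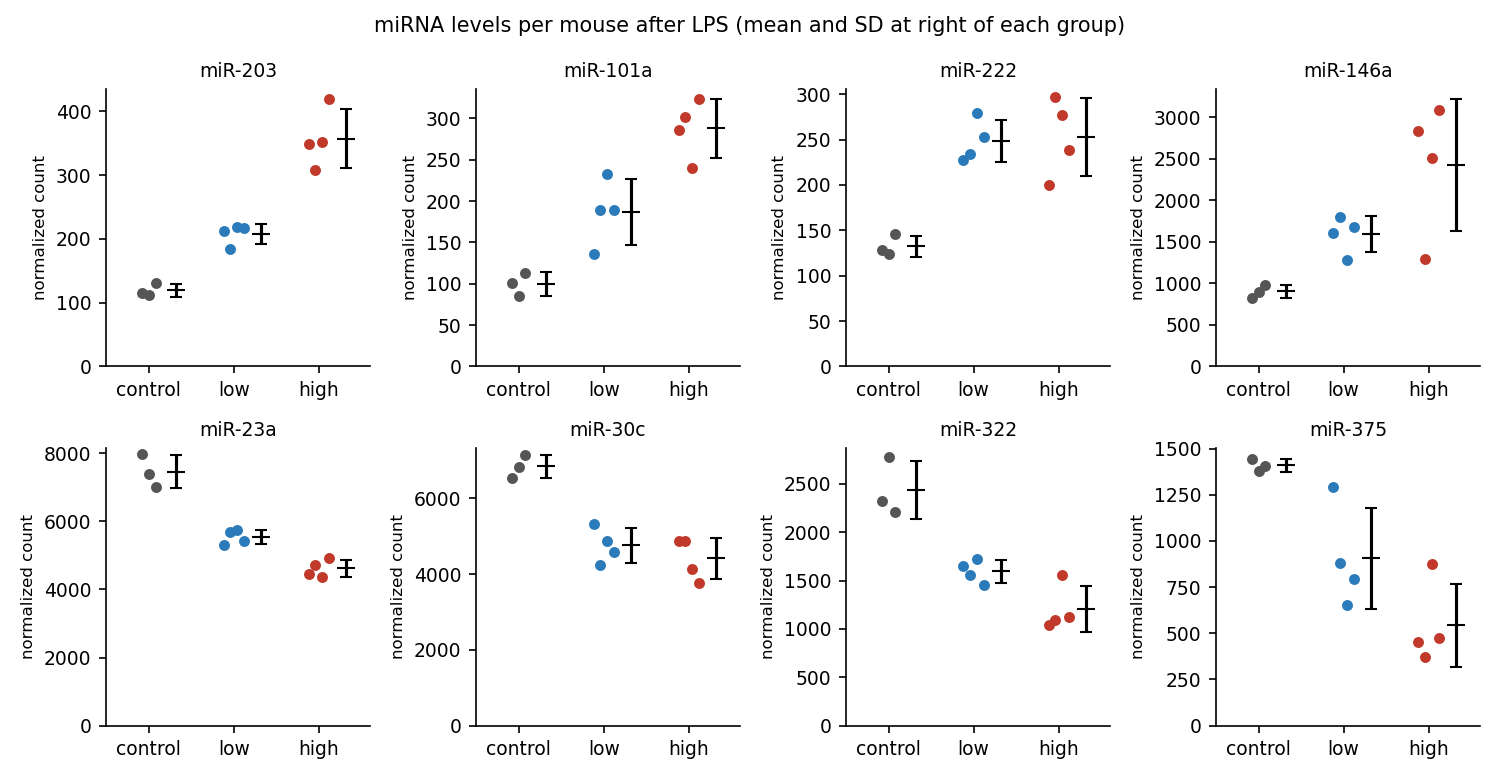
Normalized counts of 8 miRNAs (vertical axes, from 0) in each mouse of the control, low dose and high dose groups; points are mice, and the bar at the right of each group gives the mean and SD. miR-203 stood at 119 in control, 208 at the low dose and 357 at the high dose on average, while miR-375 stood at 1409, 906 and 545.

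At the high dose, 37 of 205 miRNAs passed, 21 higher and 16 lower than control. miR-203 rose to 357 ± 46.3 normalized counts (SD, n = 4), 2.99-fold over control (edgeR adjusted p = 2.85e-06), and miR-101a to 288 ± 35.5, 2.88-fold (edgeR adjusted p = 0.000141). miR-146a rose from 903 ± 74.3 to 2427 ± 794 normalized counts, 2.69-fold (edgeR adjusted p = 0.00163). miR-375, enriched in secretory and endocrine epithelium, fell from 1409 ± 34.9 to 545 ± 225 (2.58-fold, edgeR adjusted p = 0.00305), and miR-322 from 2437 ± 299 to 1204 ± 238 (2.02-fold, edgeR adjusted p = 0.000513). In 36 of the 37, the high dose mice lay outside the range of the control mice, which the choice of miRNAs by their test favours (5.71% of unselected miRNAs by chance); the exception was miR-210, named here after its values were seen.

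Further miRNAs higher at the high dose were miR-222, miR-101b, miR-26a and miR-1902, with log2 changes of 0.93, 0.93, 0.94 and 1.10. miR-155, induced in activated macrophages, rose by 0.72 ± 0.13 SE, miR-126-5p by 0.71 ± 0.14 and let-7c by 0.68 ± 0.14. miR-2183 rose by 0.81 ± 0.15, but it was above the detection bound in only 1 of 3 control mice, against 4 of 4 high dose mice, and its change ran from 0.43 to 1.30 over the alternatives, so the size is uncertain. For miR-155 the probe factor times the POS_A count exceeded the measured count in 4 of 11 lanes, including all 3 control lanes, so its fold would have no lower group if that product were background. Among those lower, miR-23a fell by 0.69 ± 0.08, miR-30c by 0.63 ± 0.11, miR-301a by 0.52 ± 0.09 and miR-27a by 0.45 ± 0.11. miR-676, miR-151-5p, miR-1896, miR-335-5p, miR-190b and miR-16 fell by between 0.28 and 0.59 on the log2 scale. With nCounter-style scaling 25 of 34 calls were higher, and with scaling to the positive controls alone 16 of 18, against 21 of 37 here. Under the latter miR-23a, miR-30c, miR-301a and miR-27a did not pass, at -0.54 ± 0.21, -0.47 ± 0.20, -0.35 ± 0.21 and -0.31 ± 0.19 SE, so smaller changes and larger errors both played a part.

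By list, 5 of the 11 LPS-responsive miRNAs rose at the high dose (miR-203, miR-222, miR-146a, miR-155 and miR-21) and 6 did not pass; adjusted over the list alone, 5 rose and 1 fell. Among those that did not pass, miR-132 stood 0.27 ± 0.21 SE above control (-0.166 with mRNA scaling), miR-146b at -0.0017 ± 0.11 and miR-125b-5p at -0.33 ± 0.12 (edgeR adjusted p = 0.0752). The list stood above the other miRNAs (camera adjusted p = 0.0151, and adjusted p = 0.311 with an estimated correlation); without the filter on low counts the adjusted p was 0.0557. The miR-30 family moved in opposite directions. miR-30b, miR-30d and miR-30e rose by 0.61, 0.45 and 0.43 on the log2 scale, miR-30c fell by 0.63, and miR-30a, named after its values were seen, did not pass (camera adjusted p = 0.515 for the 5 together; adjusted over the list alone, 4 rose and 1 fell). With mRNA scaling, which includes B2m, miR-30b, miR-30d and miR-30e shrank to 0.27 ± 0.35, 0.09 ± 0.35 and 0.08 ± 0.37 SE. miR-30c then stood at -0.95 ± 0.35, and none of the 4 passed. Over all 27 alternatives the 3 higher members reached up to 0.76, 0.62 and 0.60, and their calls ended in 1, 2 and 4. The size of their rise thus depends on the scaling. In the miR-15/16 family miR-322 and miR-16 fell and 4 of 6 did not pass (camera adjusted p = 0.319; adjusted over the list alone, 3 fell).

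The cell type lists gave no call at the high dose with camera. Of 11 epithelial miRNAs, miR-203 rose, miR-375 fell and 9 did not pass (camera adjusted p = 0.515). Of 8 myeloid miRNAs, miR-21 rose, miR-23a and miR-27a fell and 5 did not pass, and of 5 endothelial ones miR-222 and miR-126-5p rose (camera adjusted p = 0.515 for each list). The more abundant endothelial miR-126-3p, named after its values were seen, did not pass. It stood at 4455 ± 627, 4153 ± 248 and 4397 ± 591 normalized counts (SD) in control, low dose and high dose mice. No member of the lymphoid (5), ciliated cell (6), smooth muscle (5), miR-29 (3), Sfmbt2 (4), other organ (3) or Dlk1-Dio3 (15) lists passed. miR-16 fell among 5 erythroid and platelet miRNAs, let-7c rose among 9 of the let-7 family, the joint probe for miR-106a and miR-17 fell among 7 of the miR-17 clusters (a call lost in 10 of 11 fits that left out a mouse and in 22 of 27 alternatives), and miR-322 fell among 4 ovary and oocyte miRNAs. Adjusted over the list alone, 2 myeloid miRNAs rose and 2 fell, 1 of the miR-29 family rose, and 1 of the miR-17 clusters rose and 1 fell; the other lists kept the counts given. All of these lists had a camera adjusted p of 0.515 except the ciliated cell list at 0.848 and the miR-17 clusters at 0.864. The median and mean of the endothelial list had opposite signs (-0.02 and 0.26), as had those of the ciliated cell list (-0.09 and 0.0032). None of 16 listed X-linked reproductive miRNAs was detected, and 2 of 5 stress and hypoxia miRNAs were, too few for a test.

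Scaling to the mRNA reference probes uses the geometric mean of 4 probes, B2m among them. At the high dose B2m itself stood 2.26 above control (log2), against 0.05, -0.18 and 0.15 for Actb, Gapdh and Rpl19. Most of the group difference in that mean thus came from B2m, which was also uneven within the high dose. This scaling moved the median log2 change of all miRNAs at the high dose from -0.03 to -0.39. It left 2 calls, miR-375 (-1.77, edgeR adjusted p = 0.000172) and miR-322 (-1.36, edgeR adjusted p = 0.0103). All 37 kept their sign, with miR-203 at 1.20 ± 0.39 SE, miR-101a at 1.19 ± 0.38 and miR-23a at -1.05 ± 0.35, but miR-21 shrank from 0.47 ± 0.12 to 0.10 ± 0.35 and miR-26b, named after its values were seen, from 0.43 ± 0.10 to 0.10 ± 0.35, while the median standard error of the 37 grew from 0.136 to 0.358. Leaving out the 3 lanes with the highest NEG_C count left 23 calls, while 21 of the 37 passed in every fit that left out a single mouse; miR-190b was lost in 5 of these 11 fits and miR-16, miR-1896 and miR-335-5p in 4 each. Over all alternatives the call of miR-1896 ended in 14 of 27, of miR-190b in 13, of miR-16 in 12, and of miR-335-5p in 7 of 26. With scaling to the positive controls alone these 4 stood at -0.10 ± 0.21, -0.11 ± 0.21, -0.20 ± 0.22 and -0.38 ± 0.21 SE, against -0.28 ± 0.08, -0.28 ± 0.08, -0.39 ± 0.11 and -0.59 ± 0.16 here. The call of miR-151-5p also ended in 7 of 27.

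Between the doses, miR-203 alone passed: it was 1.71-fold higher at 10 µg than at 2 µg (log2 difference 0.78 ± 0.11 SE, edgeR adjusted p = 0.00141), with no overlap between the 4 mice of each group. The next miRNAs on the higher side did not pass: miR-101b differed by 0.54 ± 0.13 SE and miR-101a by 0.62 ± 0.15 (edgeR adjusted p = 0.0966 for both), followed by miR-126-5p at 0.44 and miR-2183 at 0.43. On the lower side miR-142-3p, a haematopoietic miRNA, differed by -0.52 ± 0.15 SE, miR-23a by -0.26 ± 0.08, miR-185 by -0.41 ± 0.12, miR-190b by -0.24 ± 0.07 and miR-362-3p by -0.63 ± 0.19 (edgeR adjusted p = 0.141 for each). miR-362-3p was above the detection bound in 1 of 4 high dose mice and 3 of 4 low dose mice, and its difference ran from -1.12 to -0.51 over the alternatives, so its size is uncertain. No list passed between the doses with camera (0 of 17; 1 with fry), and the LPS-responsive list had an adjusted p of 0.263. At an unadjusted p under 0.05 there were 27 miRNAs, DESeq2 called 4, and 14 passed in edgeR without high dose mouse 3, against 2 without low dose mouse 3 or high dose mouse 2. With mRNA scaling or scaling to the positive controls alone no miRNA passed between the doses in edgeR. The difference of miR-203 was then 0.58 ± 0.34 SE and 0.76 ± 0.21, against 0.78 ± 0.11 here, so the call ended mainly because the standard error grew.

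Over both doses together, a contrast not in the design text, 36 miRNAs passed, 22 higher and 14 lower, against 31 of 42 higher with nCounter-style scaling and 15 of 15 with scaling to the positive controls alone. miR-203 was 2.28-fold higher than control (log2 change 1.19 ± 0.11 SE, edgeR adjusted p = 2.66e-05), miR-101a 2.32-fold (1.22 ± 0.16, edgeR adjusted p = 0.000417) and miR-146a 2.18-fold (1.12 ± 0.22, edgeR adjusted p = 0.00480). miR-23a fell by 0.56 ± 0.07 and miR-322 by 0.81 ± 0.12. The LPS-responsive list, with 5 of 11 members higher (adjusted over the list alone, 5), had a camera adjusted p of 0.0155, and adjusted p = 0.308 with an estimated correlation. Its call ended without control mouse 2 and without the filter on low counts (adjusted p = 0.0596). The test across all 3 groups at once called 28 miRNAs, all among the 37 of the high dose. Without control mouse 2 the count over both doses was 23, and without control mouse 3 the count across groups was 18; with mRNA scaling each was 2. With that scaling 35 of the 36 kept their sign, and miR-19a, named for this contrast after its values were seen, turned from 0.28 ± 0.09 (edgeR adjusted p = 0.0430) to -0.0155 ± 0.32 SE (edgeR adjusted p = 0.981).

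All 12 miRNAs called at the low dose were also called at the high dose in the same direction, 7 higher and 5 lower, where independent lists would share 0.717 and 0.390. Independent lists would not share control mice, as these do. Simulated groups without any effect against the same controls made only 0.12 low dose and 0.05 high dose calls on average and shared 0.02. With so few calls they cannot show how much of the overlap comes from the shared controls. All 37 high dose calls had the same sign at the low dose, which the shared controls favour even without an effect. Of them 34 were larger at the high dose, a count that the choice of these miRNAs by their high dose change favours. The exceptions were miR-21, miR-27a and miR-421, the last named after its values were seen. miR-21 stood at 9238 ± 420 and 8915 ± 1423 normalized counts (SD, n = 4 each) and miR-222 at 248 ± 23.2 and 253 ± 43.1 at the low and high dose. Across the 205 miRNAs, which are not independent replicates, the log2 changes at the 2 doses had a Pearson r of 0.835 and a Spearman rho of 0.774. Simulated groups without any effect gave r = 0.574 ± 0.0615 (SD over 100 draws) and rho = 0.546 because of the shared controls. The simulated miRNAs varied independently, here and for the divided controls below. Both simulated spreads may thus be too narrow for mice whose miRNAs vary together. The covariance was 0.0974 against 0.0180 simulated, a difference of 0.0795. With the 3 controls divided between the doses in each of the 6 ways, chosen after the results were seen, r was 0.461 to 0.706 (0.0192 ± 0.0898 in 100 simulated draws without any effect, mean and SD) and the covariance 0.0714 to 0.0887. These fits, which assume that a lone control varies like the other groups, shared 0 to 4 of 0 to 8 low dose calls, all in the same direction; with fewer controls per dose they find less, and part of the overlap of calls may come from the shared controls.

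**Figure D2:**
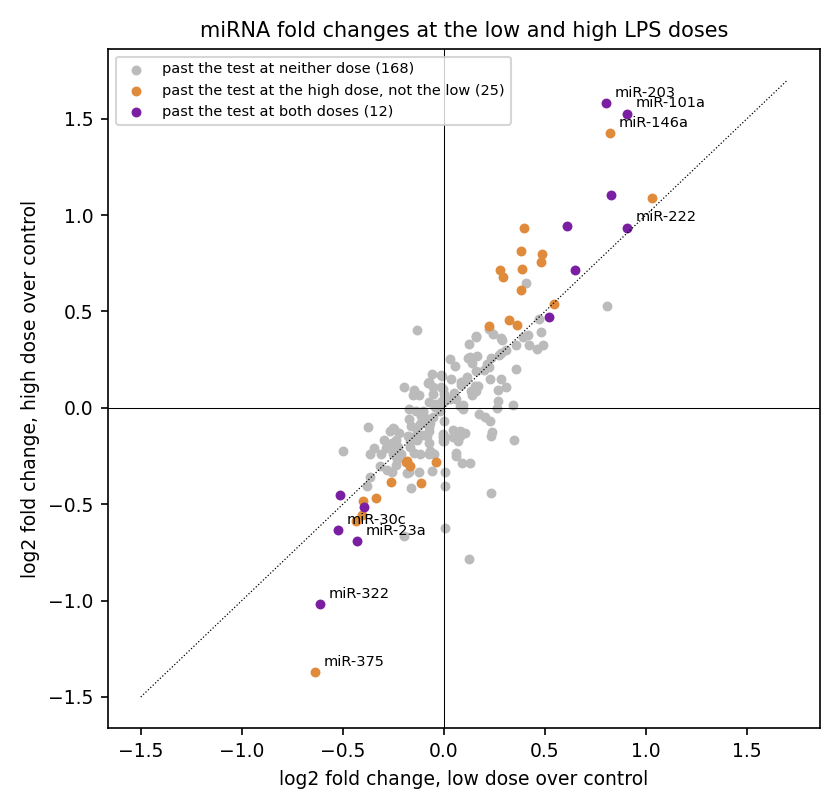
Log2 fold change over control of 205 miRNAs at the low dose (horizontal) and high dose (vertical); each point is a miRNA, coloured by the doses at which it passed the edgeR test, and the dotted line marks equal change. The 12 miRNAs past the test at both doses lie in the same direction at each, and miR-375 lies lowest at the high dose (-1.37).

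Of the mRNA reference probes, B2m, the light chain of MHC class I molecules, stood at 732 ± 100.9 counts in control mice (SD, n = 3), 2863 ± 816 at the low dose and 4361 ± 2397 at the high dose (n = 4 each). Its exact permutation p across the groups was 0.0308, which became 0.123 after adjustment over the 4 probes, so no probe passed. All 8 LPS mice lay above the 3 control mice (exact permutation p = 0.00606, two-sided, unadjusted), with a 4.25-fold difference. The high dose group was uneven: mouse 2 stood at 884 counts and the other mice between 4701 and 6161. Without that mouse B2m passed (exact permutation adjusted p = 0.00190). Actb stood at 2553 ± 84.4, 2526 ± 361 and 2700 ± 589 counts, Gapdh at 185 ± 24.5, 151 ± 10.8 and 164 ± 27.3, and Rpl19 at 1588 ± 48.3, 1590 ± 147 and 1779 ± 253, with exact permutation adjusted p of 0.918, 0.385 and 0.460. With TMM factors the differences of Actb and Rpl19 between LPS and control mice turned from 0.01 and 0.07 to -0.17 and -0.11 on the log2 scale.

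**Figure D3:**
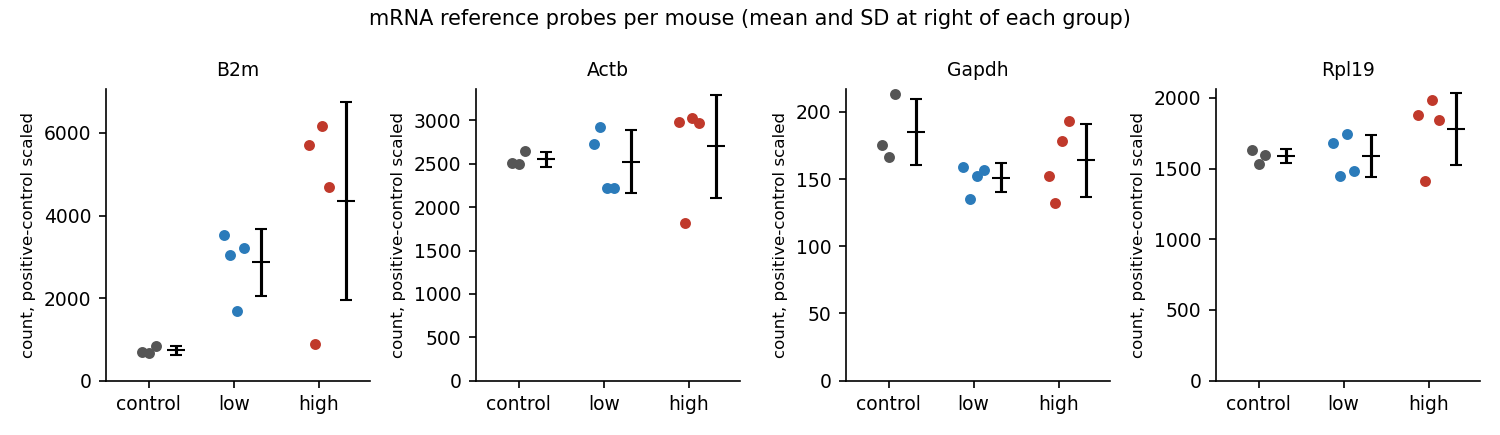
Counts of the 4 mRNA reference probes scaled to the positive controls (vertical axes, from 0) in each mouse of the control, low dose and high dose groups; points are mice, and the bar at the right of each group gives the mean and SD. B2m lay between 660 and 847 in control mice, and at 884 in high dose mouse 2.

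None of the 33 viral miRNA probes was above the bound in 3 or more lanes, and 2 were in any lane. The ratio of ligation controls to positive controls was 1.16-fold higher in LPS mice (exact permutation p = 0.20, two-sided). The 3 spike-in probes had mean counts of 11.7, 7.0 and 12.0, at the level of the negative controls.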

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

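The comparison of the LPS-responsive list with treatment, both tests of miR-155, and both tests of high dose mouse 2 were chosen only after the results were seen.

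In 7 of 148 groups of 4 mice, 1 mouse lay far from the rest of its group, where chance gives about 1 in 20. miR-203 stood at 185 normalized counts in low dose mouse 2, below the 212 to 218 of the other low dose mice. miR-322 stood at 1557 in high dose mouse 3, above the 1041 to 1128 of the others in its group. miR-29b stood at 14499 in low dose mouse 2 (others 16234 to 16426), and miR-15a at 2601 in high dose mouse 1 (others 1838 to 1967). miR-362-3p stood at 92.5 in high dose mouse 3 (others 47.1 to 51.5). The detection bound of high dose mouse 2 was 97.9 counts (others 68.2 to 72.1). miR-203 differed between the doses by 0.78 ± 0.11 SE on the log2 scale (edgeR adjusted p = 0.00141), which became 0.58 ± 0.34 with mRNA scaling and 0.76 ± 0.21 with scaling to the positive controls alone, neither past the threshold.

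At the high dose 37 miRNAs differed from control, miR-203 and miR-375 among them. Drift along the lane order as the whole cause would need a slope of 1 between lane trends within groups and group differences; the slope was 0.348 ± 0.241 (jackknife SE), so a partial contribution stays open because lanes ran in group order. With the ligation ratio as a covariate the changes kept 0.979 ± 0.0413 of their size, which argues against ligation efficiency. The LPS-responsive list stood above the other miRNAs at both doses (larger camera adjusted p = 0.0288), as a response to LPS would predict. This call is lost with an estimated correlation (camera adjusted p = 0.398 and 0.311). As given below, 20 of 35 splits of the mice at the low dose and 14 of 35 at the high dose called as many lists. The called members of the list are among the 37 miRNAs, so the list is not separate evidence. Of these members, miR-203, miR-222 and miR-21 also stand in the epithelial, endothelial and myeloid lists. Calls fell to 2 with mRNA scaling and 18 with scaling to the positive controls alone, but all 37 miRNAs kept their sign under both; the median change of the higher ones went from 0.75 to 0.42 and 0.93, that of the lower ones from -0.48 to -0.83 and -0.30, and the median standard error from 0.136 to 0.358 and 0.224, so the lost calls reflect the larger error as well as the shift.

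miR-155 was higher in LPS mice by 0.55 ± 0.11 SE on the log2 scale. Its probe carries a factor of unstated use, and if its counts were signal of the POS_A control their ratio would not differ between groups. The ratio differed by 0.786 ± 0.0990 (jackknife SE, log2), which argues against POS_A signal as the source of all the counts. It was taken on raw counts, so it also holds any change in POS_A. POS_A signal as a part of the counts stays open, since the factor times POS_A exceeded the count in all 3 control lanes. The size of the change is therefore uncertain. More blood-derived cells would raise other leukocyte miRNAs by about as much, but the median of miR-142-3p, miR-142-5p, miR-223 and miR-150 was -0.0310 ± 0.0786 (jackknife SE, log2). Singly they stood at 0.09, -0.04, -0.28 and -0.02 over both doses, and none passed. The pooled median hides differences between doses: miR-142-3p averaged 1358, 1728 and 1207 normalized counts in control, low dose and high dose mice. A change of miR-155 within cells of the oviduct, and a change in a leukocyte type poor in these miRNAs, were not tested and stay open.

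B2m stood at 884 counts in high dose mouse 2, near the control mice, and Actb at 1818, below the 2975 to 3031 of the others in its group. A control-like animal is argued against by its miRNAs, which stood at 0.905 of the shift of the other high dose mice over 32 miRNAs, where those mice ranged from 0.75 to 1.23 and control mice from -0.0753 to 0.0790. Low mRNA recovery in that lane would lower all mRNA probes alike, but Actb, Gapdh and Rpl19 lay lower by 0.515 ± 0.178 (log2, mean and SD) and B2m by 2.63. Low recovery could therefore account for part of the B2m deficit and not the whole. No biological explanation was tested for this mouse, since the design names none.

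The counts were set beside those of other splits of the mice. With 35 splits the smallest share possible is 1 of 35, and shares were not adjusted for the number of counts. A real split with the highest count therefore makes chance less likely but does not exclude it. Across the 3 groups 1 of 100 splits, the real one, gave 28 or more miRNAs (highest other 14), and for both doses together 1 of 100 gave 36 or more (highest other 13). For the low dose 1 of 35 splits gave 12 or more (highest other 1), and for the high dose 1 of 35 gave 37 or more (highest other 20). For the single call between the doses 5 of 35 splits gave 1 or more (highest other 1), so chance could readily give a count of 1. The splits compare counts only and do not weigh how strong the call of miR-203 was (edgeR adjusted p = 0.00141). Chance could also readily give the number of lists called. At the low dose 20 of 35 splits called as many as the real split (real 1, highest other 3). At the high dose 14 of 35 did (real 1, highest other 2). Between the doses 35 of 35 did (real 0, highest other 4), and for both doses together 29 of 100 (real 1, highest other 3).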

How the results depend on the processing

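Scaling to the positive controls alone, the divided controls, the POS_A subtraction, the bound without NEG_C, leaving out the 3 lanes with the highest NEG_C or the 2 LPS mice with the lowest B2m, and the ligation covariate were chosen only after the results were seen. Across alternatives, 195 values of the main counts, lists and correlation stayed on their side or within 1.5 times, 30 were weaker, 28 stronger and 6 moved. Of values of named probes, 3175 kept their side and direction, 290 were weaker, 61 stronger and 57 reversed, none of which had passed. Outside these values, miR-19a passed for both doses together at 0.284 and reversed to -0.0155 with mRNA scaling; it was named there after its values were seen. miR-322 and miR-375 passed at the high dose in all 27 alternatives computed for them. Counts are given below in the order across groups, low dose, high dose, between doses and both doses together, and the cause of a change was not tested unless stated. Depth limits the miRNAs with lower counts, where counting noise would give a median share of 0.454 of the variance between mice, against 0.0296 in the others. The median log2 change of all miRNAs moved to -0.20 (low), -0.39 (high), -0.15 (between doses) and -0.29 (both) with mRNA scaling. With scaling to the positive controls it moved to 0.18, 0.12, -0.0093 and 0.15. The mRNA scale includes B2m, which itself was 4.25-fold higher in LPS mice.

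With mRNA scaling the counts were 2, 0, 2, 0 and 2, and with scaling to the positive controls 13, 8, 18, 0 and 15, with 0 lists at the low dose. DESeq2 gave 20 at the low dose, where it left 60 miRNAs without an adjusted p, and 4 between doses, where it left 0. One-way analysis of variance at an unadjusted p under 0.05 gave 56 across groups, 38 at the low dose and 25 between doses, and with Benjamini-Hochberg adjustment 2 between doses. Looser thresholds called more by construction: an adjusted p of 0.1 gave 24, 58, 3 and 59 (low, high, between, both), and an unadjusted p of 0.05 gave 66, 56, 68, 27 and 68. Without the 3 highest NEG_C lanes, with fewer mice, the counts were 14, 3, 23 and 15 (across groups, low, high, both). Without the 2 mice with the lowest B2m they were 18 across groups, 7 at the low dose and 2 between doses. Without the filter, 0 lists were called at the low dose and 1 between doses, where the miR-15/16 family was lower (camera adjusted p = 0.0318); at the high dose and for both doses that family (adjusted p = 0.00158 and 0.00607) took the place of the LPS-responsive list. With an estimated correlation 0 lists passed at the low dose, high dose or both doses, and fry, which does not compare a list with other miRNAs, called 3, 7, 1 and 6. The filter at a mean of 50 normalized counts removed 0 miRNAs and tests nothing.

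Leaving out each mouse gave 18 to 31 miRNAs across groups, 3 to 13 at the low dose, 25 to 40 at the high dose, 1 to 14 between doses and 23 to 48 for both doses. The lowest low dose counts came without low dose mouse 4 (3), control mouse 2 (4) and control mouse 1 (6), and the 14 between doses without high dose mouse 3. Lists called ranged from 0 to 1 at the low dose, 1 to 1 at the high dose, 0 to 2 between doses and 0 to 1 for both, the correlation from 0.776 to 0.857 and the mRNA probes called from 0 to 1 (B2m, without high dose mouse 2). With the replicate block the counts were 22, 11, 28, 1 and 27, no list call changed, and the correlation was 0.814. With control mouse 1, 2 or 3 alone for the low dose and the other controls for the high dose the correlation was 0.461, 0.605 and 0.706, and with each alone for the high dose 0.603, 0.582 and 0.672; a lone control lowers it by its own noise too. The numbers are not taken as pairs: same-numbered mice correlated from -0.29 to 0.40, 2 of 10 pairs over 0.1, and 3 of 11 mice correlated best with their own number.

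Reversed values, as log2 changes against control, were as follows. miR-146b at the high dose was 0.00919 with RLE, 0.0580 with nCounter-style and 0.160 with positive-control scaling, 0.00836 above the bound in every lane, 0.00802 after background subtraction, 0.00897 in DESeq2, 0.00185 in limma-voom, 0.0157 without NEG_C in the bound, 0.0494 without the highest NEG_C lanes or the lowest B2m mice, and -0.0844 to 0.0697 leaving out each mouse. miR-181c at the low dose was 0.0167 with nCounter-style and 0.159 with positive-control scaling, 0.00367 above the bound in every lane, 0.00135 without NEG_C in the bound, 0.00963 without the highest NEG_C lanes, 0.00349 with the ligation covariate, and -0.0983 to 0.0960 leaving out each mouse. At the high dose miR-181c was -0.0178 without the filter and -0.0269 to 0.146 leaving out each mouse. miR-290-3p at the high dose was -0.0341 without the highest NEG_C lanes, -0.0337 without the lowest B2m mice, and -0.0426 to 0.266 leaving out each mouse. With positive-control scaling miR-125b-5p and miR-25 at the low dose were 0.0574 and 0.0178. With mRNA scaling miR-132, miR-29a and miR-29b at the low dose were -0.0457, -0.0613 and -0.106. At the high dose with mRNA scaling miR-132 was -0.166, miR-181c -0.368, miR-24 -0.0142, miR-34a -0.153, miR-19a -0.0946, miR-29a -0.131, miR-29c -0.232, miR-669f -0.0195, miR-290-3p -0.150 and miR-129-3p -0.0998. miR-543 at the low dose was 0.405 after the POS_A subtraction. With TMM factors Actb and Rpl19 were -0.170 and -0.108, and leaving out each mouse Actb ranged from -0.0215 to 0.0838.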

Other observations

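No test in this part was chosen only after the results were seen; the pairs named as examples were.

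Neighbouring miRNAs gave both like and unlike changes at the high dose, and no difference between members of a pair was tested. Some have more than 1 gene: miR-24 also lies beside miR-23b and miR-27b, and miR-16 beside miR-15b. Their counts can sum over genes, so such a pair need not compare products of 1 transcript. In the cluster of miR-23a, miR-27a and miR-24, miR-23a and miR-27a fell by 0.69 and 0.45 on the log2 scale, while miR-24 stood 0.37 above control (-0.0142 with mRNA scaling) and did not pass. miR-222 rose by 0.93, while miR-221 of the same cluster stood at -0.24 and did not pass. miR-30b and its neighbour miR-30d rose by 0.61 and 0.45, and miR-16 fell by 0.39 with miR-15a beside it at -0.36, which did not pass. miR-30c fell by 0.63 and its neighbour miR-30e rose by 0.43. Whether all miR-30c counts come from the gene beside miR-30e was not tested, so this pair too need not compare products of 1 transcript. With mRNA scaling miR-30b, miR-30d and miR-30e stood at 0.27 ± 0.35, 0.09 ± 0.35 and 0.08 ± 0.37 SE and did not pass. Over all 27 alternatives they reached up to 0.76, 0.62 and 0.60, and their calls ended in 1, 2 and 4.

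The hypothesis that miRNAs of neighbouring genes change alike was tested over 78 pairs of detected miRNAs whose genes lie within 10 kb in assembly GRCm38.p6, with 177 miRNAs located and 25 not. Their median difference in log2 change was 0.25, against 0.32 when changes were permuted among miRNAs (permutation p = 0.0937, 0.187 after Benjamini-Hochberg adjustment over 2 tests, 10000 permutations). The test leaves open whether shared transcription contributes. For 70 pairs that share their number the median difference was 0.28, against 0.32 permuted (permutation p = 0.280, adjusted p = 0.280). A shared number is only a rough stand-in for a shared sequence. The pairs included opposite arms, such as miR-125a-3p with miR-125b-5p, and many let-7 pairs. They left out relatives with other numbers, such as miR-15a and miR-16. The test therefore does not decide whether a shared family sequence brings changes together.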
